A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

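RNA-seq libraries were made from total RNA of 3 Saccharomyces cerevisiae strains described in the series as producers of diosgenin, a plant steroidal sapogenin. The strains LP085-Vc, LP104-17 and LP118 share the laboratory background BY4742, and the labels give no genotype and no list of introduced genes. Cells came from flask cultures in synthetic dextrose medium, harvested at 6 h and at 24 h, with 3 libraries per strain and time and 18 libraries in all. RNA was extracted with Trizol and cleaned on columns with DNase I, per the labels' protocols, and libraries followed a standard Illumina protocol. No label says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

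Each library had a table of 6600 genes with a coding length, a raw count and an FPKM value. The counts are whole-number read counts per gene that the authors deposited without normalization, per the file headers and the values. The FPKM values are the authors' own, per the file headers, and each equals the deposited count scaled by coding length and by a library denominator to within 5e-10. One file repeats the count header over its FPKM column, and the values identify that column as FPKM. Reads were aligned with Bowtie2 2.2.5 to build R64, per the submitters' processing notes. The counting tool, its annotation, its use of strand and any read filter are not given in the sources used here. Reads from genes that overlap on either strand, or that share sequence with a close copy, could therefore not be assigned with certainty, and values of such genes are uncertain. HYP2, an abundant translation factor gene, had 0 counts in every library, so an exact count of 0 is not read as an absent transcript, and its cause was not tested. Of 81 reference genes with 0 counts in all libraries, 61 had 0.5 or more of their windows repeated in the genome.

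Gene identifiers were matched to the RefSeq annotation of build R64 to obtain symbols and coordinates. Of the 6600 identifiers, 5917 matched (89.7%) and 683 did not, and coding lengths were equal for 5888 of the matched genes. Another 104 coding loci of the reference had no value in the tables, 91 of them annotated as gag, pol or transposon genes. Total counts per library, in units of 1e6, ran from 5.12 to 7.55, a 1.47-fold range, and 6235 to 6315 genes had at least 1 count. For genes with counts in 1 group and none in the other, a floor of 3 counts in each library of that other group was used. Ratios with 1 to 3 counts in the lower group have 95% counting intervals. Intervals and floors cover counting error only.

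Differences were tested with edgeR 4.0.16 in R 4.3.3. One quasi-likelihood model was fitted to the counts of all 18 libraries with a mean for each of the 6 groups, TMM scaling (factors 0.914 to 1.11) and 12 residual degrees of freedom. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 6131 tested genes and removed 469. The tests were the 6 differences between strains at each time, the 3 changes over time within a strain, and the 3 interactions, which are differences between strains in the change over time. All are two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Fold changes are given as log2 fold change ± standard error (SE) with a prior count of 0.125, and expression as counts per 1e6 counts (CPM) of TMM-scaled libraries, mean ± SD, n = 3. The biological coefficient of variation was 11.2%.

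Gene lists were tested with camera in limma 3.58.1, which compares a list's genes with the other tested genes at a preset correlation of 0.01. Its p-values were adjusted over the 43 lists with tested genes, of 45 lists that cover metabolism, stress, sterol and cell type functions. The lists hold 773 tested genes. The mitochondrial genome list had 8 genes in the tables and 0 tested, and the list for the 2-micron plasmid had 0 genes in the tables. Each list was also tested with a correlation estimated from the data, and each member was also tested with its p adjusted over the list alone. Overlap between the comparisons with LP085-Vc was set beside unchanged groups simulated against the same control libraries and beside the overlap of independent lists.

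The groups, the tests, the gene lists, the rule for naming genes and the settings listed first below were fixed before the data were examined. The rule takes, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes with a symbol, at least 10 CPM in the higher group and no overlap between the libraries of the groups. For interactions it takes 5 in each direction without the condition on overlap. It adds up to 4 members with the smallest adjusted p of each list called by camera in that comparison. It also allows every gene of the lists for the mevalonate pathway, squalene to ergosterol, P450 partners, heme, the galactose regulon, pleiotropic drug resistance, the auxotrophic marker loci, alpha cells and a cells. No overlap between 3 libraries and 3 others arises by chance for 10% of genes.

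Other settings chosen beforehand were DESeq2 1.42.0, its median-ratio scaling (RLE), no filter on low counts, the replicate number as a block, a fit of only the groups compared, and limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1). Each library was also left out in turn. For lists, the alternatives were an estimated correlation, fry, the block and RLE, and for overlaps a threshold of 2-fold. Alternatives added after seeing the data removed the trend of each library with coding length, left out the genes of chromosomes V and IX, and extended the other settings to the lists, overlaps and correlations.

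The procedure was tested on simulated counts with known changes. For the comparison of LP104-17 with LP085-Vc at 6 h (6112 genes) it recovered 64.2% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold, with 10 false calls among 180. For the interaction between LP118 and LP085-Vc (6107 genes) the shares were 28.4%, 82.1% and 89.4%, with 4 false calls among 137. The simulated counts varied independently between genes, without trends common to the genes of a library. These rates therefore need not hold for real libraries that carry such trends. Paralogs were screened in the reference: among the named genes, 24 had at least 10% of their windows elsewhere in the genome, led by HXT6 and HXT7 (95.1% each), SSA2 (58.2%), SSA1 (57.9%) and TPO2 (41.3%). LYS20, IMD2, TDH1, TDH2, TDH3, ENO1, ENO2, HXT3, MF(ALPHA)1, ADH2 and TIR1 were also among these 24, and the values of all 24 may mix reads of close copies.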

Results

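The 6 groups lay apart on the first 2 principal components of the 18 libraries. The first principal component held 64.1% of the variance of log2 CPM, the next 19.5% and the one after it 5.19%. Pearson correlations across genes ran from 0.968 to 0.993 between libraries of a group and from 0.581 to 0.982 between libraries of different groups, so the 2 ranges overlapped. Total counts, in units of 1e6, averaged 6.82 ± 0.65 (SD, n = 3) at 6 h and 7.12 ± 0.26 at 24 h in LP085-Vc, 6.37 ± 0.95 and 6.64 ± 0.45 in LP104-17, and 5.21 ± 0.11 and 6.24 ± 0.32 in LP118.

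**Figure D1:**
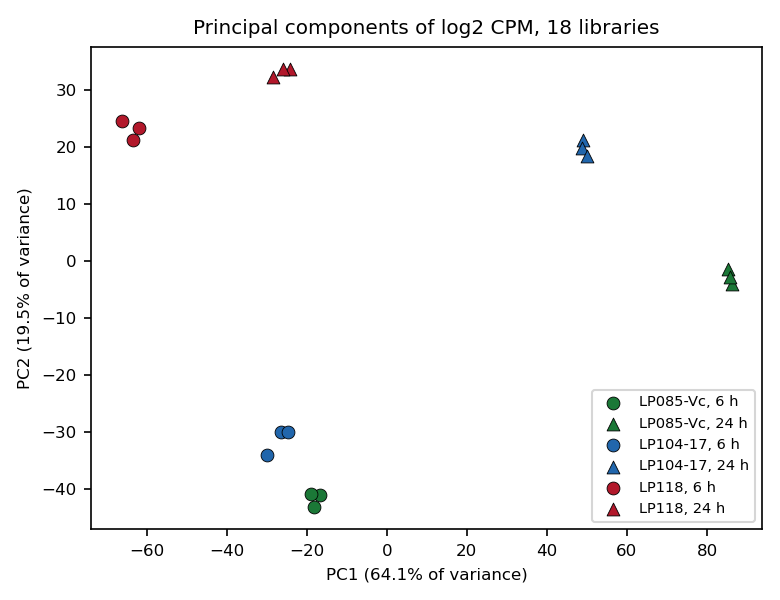
Each point is 1 of the 18 libraries placed on the first and second principal components of log2 CPM, which hold 64.1% and 19.5% of the variance. The 6 groups of 3 libraries lie apart, and the LP118 libraries at 24 h lie away from the other libraries of that time.

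Of the 4 auxotrophic marker loci (HIS3, LEU2, LYS2 and URA3) and TRP1, the counts of LEU2, TRP1 and URA3 told the 3 strains apart. LEU2 (isopropylmalate dehydrogenase, R64 chromosome III, 91324 to 92418) had 0 counts in the 3 LP085-Vc libraries at 6 h. It reached 30.2 ± 0.446 CPM in LP104-17, at least 67.8-fold higher, and 124 ± 6.73 CPM in LP118, at least 280-fold higher. At 24 h, LP085-Vc had 1 LEU2 count, and the ratios were 265 (counting interval 48.2 to 10600) for LP104-17 and 1500 (273 to 59900) for LP118. TRP1 (phosphoribosylanthranilate isomerase, chromosome IV, 461842 to 462516) had 3 counts in LP085-Vc at 6 h and 2 at 24 h. Its ratio to LP085-Vc was 436 (144 to 2030) in LP104-17 and 839 (276 to 3910) in LP118 at 6 h, and 933 (250 to 7450) and 1450 (388 to 11600) at 24 h. URA3 (orotidine-5-phosphate decarboxylase, chromosome V, 116167 to 116970) had 1 count in LP104-17 at 6 h, against 204 ± 13.1 CPM in LP085-Vc and 704 ± 5.31 CPM in LP118. The ratios to LP104-17 were 4570 (721 to 158000) and 15800 (2490 to 545000). At 24 h URA3 had 0 counts in LP104-17 and was at least 926-fold higher in LP085-Vc and at least 960-fold higher in LP118.

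HIS3 transcripts were present in every group, from 235 ± 27.3 CPM in LP085-Vc at 6 h to 587 ± 47.2 CPM in LP118 at 24 h. LYS2, the aminoadipate reductase gene, was low in LP085-Vc (6.63 ± 1.15 CPM at 6 h) and higher in LP118 (47.0 ± 3.49 CPM, log2 fold change over LP085-Vc 2.82 ± 0.30). In LP118, the 4 marker loci were all higher than in LP085-Vc at 6 h (4 higher, 0 lower, 0 not called, adjusted p = 5.72e-06) and than in LP104-17 at 6 h (4 higher, 0 lower, 0 not called, adjusted p = 5.06e-09) and at 24 h (4 higher, 0 lower, 0 not called, adjusted p = 1.63e-06). These 3 calls held with an estimated correlation. They rest in part on LEU2, with 0 counts in LP085-Vc at 6 h, or on URA3, with 1 and 0 counts in LP104-17 at 6 h and 24 h. In LP118 against LP085-Vc at 24 h, URA3 did not differ (log2 fold change 0.05 ± 0.09, adjusted p = 0.59).

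Calls in LP104-17 against LP085-Vc at 6 h included genes of amino acid and purine synthesis, stress and glucose transport. Lysine synthesis rose, with LYS1 (saccharopine dehydrogenase) up from 377 ± 28.6 to 1232 ± 52.8 CPM (log2 fold change 1.71 ± 0.10), LYS9 by 1.80 ± 0.08 and LYS4 by 1.52 ± 0.08. Genes of sulfate assimilation and methionine synthesis fell, among them STR3 (cystathionine beta-lyase, -1.96 ± 0.13), MET3 (ATP sulfurylase, -1.80 ± 0.10) and MET1 (-1.70 ± 0.08). Purine synthesis rose, led by ADE17 (1.60 ± 0.10) and MTD1 (1.13 ± 0.10). Stress genes were lower, including HSP30 (-1.92 ± 0.16) and HSP26 (-1.16 ± 0.09), and so were the high-affinity glucose transporter genes HXT6 (-2.21 ± 0.16) and HXT7 (-2.13 ± 0.17), whose sequences are near copies, and their regulator MTH1 (-1.50 ± 0.09).

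In that comparison 708 of 6131 genes were called, 355 higher and 353 lower, with 26 up and 47 down at least 2-fold. On log2(FPKM + 1) the split was 397 higher and 261 lower, a share of higher calls of 60.3% against 50.1%, and on log2(FPKM + 0.1) it was 396 and 259. In a fit of only these 2 groups 344 genes were called, and 1206 without LP104-17 6 h replicate 2. Changes followed coding length: Spearman's rho across genes was 0.281, and the 25% of genes that were shortest had a median of -0.0841 against 0.105 in the 25% that were longest. With that trend removed 937 genes were called, 673 of them in both fits in the same direction. A split of the same libraries across the strains called 1302 genes, more than the strains did, so a structure besides the strain may enter these calls.

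Ribosome biogenesis rose in LP104-17 at 6 h (37 higher, 0 lower, 12 not called or 41 higher and 0 lower adjusted over the list alone, adjusted p = 8.48e-23), with the nucleolar protein gene NSR1 at 1.13 ± 0.13, and lysine synthesis rose as a list (6 higher, 0 lower, 3 not called or 8 higher and 0 lower adjusted over the list alone, adjusted p = 3.68e-39). Sulfur and methionine fell (0 higher, 18 lower, 2 not called or 0 higher and 19 lower adjusted over the list alone, adjusted p = 3.26e-48), and purine synthesis rose (12 higher, 0 lower, 4 not called or 14 higher and 0 lower adjusted over the list alone, adjusted p = 1.27e-24). The environmental stress response was lower (0 higher, 24 lower, 10 not called or 0 higher and 28 lower adjusted over the list alone, adjusted p = 6.98e-30). Hexose transporters fell (0 higher, 5 lower, 6 not called or 0 higher and 6 lower adjusted over the list alone, adjusted p = 4.27e-12), as did Hsf1 chaperones (0 higher, 8 lower, 12 not called or 0 higher and 10 lower adjusted over the list alone, adjusted p = 2.7e-06). These 7 lists held with an estimated correlation. Adjusted p-values of lists are camera's, and where no second count is given, here and for every other comparison, the count adjusted over the list alone was the same. Nitrogen catabolite repression, the genes for poor nitrogen sources, was higher (6 higher, 0 lower, 14 not called or 11 higher and 0 lower adjusted over the list alone, adjusted p = 1.82e-06), with the ammonium permease gene MEP2 at 0.98 ± 0.10, but adjusted p = 0.113 with an estimated correlation. The iron regulon was lower (0 higher, 8 lower, 12 not called or 0 higher and 10 lower adjusted over the list alone, adjusted p = 1.47e-06), with FIT2, a siderophore-binding cell wall protein gene, at -1.30 ± 0.10, but adjusted p = 0.105 with an estimated correlation. Ribosomal proteins were higher (17 higher, 0 lower, 121 not called or 22 higher and 0 lower adjusted over the list alone, adjusted p = 4.27e-08), a call lost with fry (adjusted p = 0.0792) and not held at adjusted p = 0.632 with an estimated correlation. Other lists, 2 higher and 3 lower, lost the call with an estimated correlation (adjusted p = 0.0564 to 0.433).

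Pyrimidine synthesis had a median of 0.18 in that comparison and a mean of -0.90, which rests on the fitted value of URA3 with 1 count, and its test pointed down (3 higher, 1 lower, 6 not called, adjusted p = 0.043; adjusted p = 0.247 with an estimated correlation). It lost its call without LP104-17 6 h replicate 1 (adjusted p = 0.0939), replicate 2 (0.24) or replicate 3 (0.0556) and with the block (0.0645). Without the genes of chromosomes V and IX, URA3 among them, it pointed up (adjusted p = 0.00448). Glycolysis was lower (0 higher, 3 lower, 14 not called or 0 higher and 6 lower adjusted over the list alone, adjusted p = 0.00556; adjusted p = 0.626 with an estimated correlation), and lost its call without LP085-Vc 6 h replicate 1 (0.108) or LP104-17 6 h replicate 2 (0.0706).

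LP118 at 6 h had a higher expression of the genes that build ribosomes than LP085-Vc and a lower expression of stress genes. NSR1 rose from 26.3 ± 1.69 to 663 ± 114 CPM (log2 fold change 4.66 ± 0.13) and DBP2, an RNA helicase gene, by 4.38 ± 0.15. The glycogen synthase gene GSY1 fell by 5.42 ± 0.12 in log2, HSP26 by 4.17 ± 0.10 and SPI1, on chromosome V, by 4.97 ± 0.10. TDH1, a glyceraldehyde-3-phosphate dehydrogenase isoform gene, dropped from 6953 ± 593 to 175 ± 16.8 CPM, and TIR1, a cell wall mannoprotein gene on chromosome V, from 1673 ± 428 to 4.80 ± 1.74 CPM. Lower as well were INO1 (inositol-3-phosphate synthase, -4.02 ± 0.08), CHO1 (phosphatidylserine synthase, chromosome V, -2.45 ± 0.12), the endoplasmic reticulum folding genes ERO1 (-1.58 ± 0.09) and KAR2 (-1.36 ± 0.09), and the Hsp70 gene SSA4 (chromosome V, -4.04 ± 0.08).

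Of 6131 genes 4049 were called in LP118 against LP085-Vc at 6 h, 1974 higher and 2075 lower, with 854 up and 785 down at least 2-fold. These changes followed coding length too (rho 0.19), with a median of -0.253 in the 25% of genes that were shortest and 0.226 in the 25% that were longest. With that trend removed 92.3% of the calls were kept and 10 were called in the opposite direction, and the split was 1839 higher and 2330 lower, a share of higher calls of 44.1% against 48.8%. Ribosome biogenesis was higher in full (49 higher, 0 lower, 0 not called, adjusted p = 2.12e-50) and the environmental stress response lower (1 higher, 32 lower, 1 not called, adjusted p = 3.12e-33). Leucine, isoleucine and valine synthesis was higher (12 higher, 0 lower, 1 not called, adjusted p = 3.46e-11), with LEU1 at 2.43 ± 0.10 and OAC1, a mitochondrial carrier gene, at 2.32 ± 0.09. In every comparison this list holds the marker locus LEU2, with 0 counts in LP085-Vc at 6 h, and it was not tested without LEU2. Sulfur and methionine was lower (0 higher, 18 lower, 2 not called, adjusted p = 6.64e-12), with STR3 at -4.77 ± 0.17. Hsf1 chaperones were lower (3 higher, 16 lower, 1 not called, adjusted p = 2.7e-07), with the Hsp90 gene HSP82 at -1.47 ± 0.07. Lower too were inositol-regulated phospholipid synthesis (1 higher, 12 lower, 0 not called, adjusted p = 3.34e-06) and the unfolded protein response (1 higher, 16 lower, 1 not called, adjusted p = 0.00024). So were oxidative stress (3 higher, 18 lower, 2 not called, adjusted p = 4.03e-05) and galactose genes (0 higher, 7 lower, 1 not called, adjusted p = 5.72e-06). These calls and that of the marker loci held with an estimated correlation. Ribosomal protein genes were higher (127 higher, 0 lower, 11 not called or 129 higher and 0 lower adjusted over the list alone, adjusted p = 3.31e-17), but adjusted p = 0.366 with an estimated correlation. Histidine and tryptophan synthesis was higher (15 higher, 0 lower, 1 not called, adjusted p = 4.11e-06; adjusted p = 0.0981 with an estimated correlation) and the tricarboxylic acid cycle lower (1 higher, 12 lower, 2 not called, adjusted p = 0.0019; adjusted p = 0.225 with an estimated correlation). The histidine and tryptophan list holds HIS3 and TRP1, the latter with 3 counts in LP085-Vc at 6 h, and was not tested without them. Other lists, 2 higher and 3 lower, lost the call with an estimated correlation (adjusted p = 0.134 to 0.639).

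Against LP104-17, LP118 at 6 h was lower in lysine genes, with log2 fold changes of -3.84 ± 0.09 for LYS9 and -2.29 ± 0.07 for LYS20. MEP2 (-3.46 ± 0.11) and the general amino acid permease gene GAP1 (-2.94 ± 0.11) were lower, but their list, nitrogen catabolite repression, had 6 genes higher and 11 lower and lost its call with an estimated correlation (adjusted p = 0.255). Carbonic anhydrase NCE103 was higher (3.60 ± 0.11), and so were OAC1 (3.10 ± 0.10), LEU1 (3.07 ± 0.10) and NSR1 (3.52 ± 0.12). INO1 (-3.87 ± 0.08), SSA4 (chromosome V, -3.38 ± 0.08) and GSY1 (-4.55 ± 0.12) were lower, as against LP085-Vc.

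Called genes in this comparison numbered 3586, 1761 higher and 1825 lower, with 668 up and 593 down at least 2-fold. The median of all genes on log2(FPKM + 1) was -0.11. Ribosome biogenesis (49 higher, 0 lower, 0 not called, adjusted p = 1.7e-47) and branched-chain amino acid synthesis (11 higher, 1 lower, 1 not called, adjusted p = 9.92e-14) were higher. Lysine synthesis was lower (1 higher, 8 lower, 0 not called, adjusted p = 4.53e-07). So were the environmental stress response (0 higher, 28 lower, 6 not called, adjusted p = 5.25e-27) and phospholipid synthesis (1 higher, 10 lower, 2 not called or 1 higher and 11 lower adjusted over the list alone, adjusted p = 4.11e-07). Lower as well were Hsf1 chaperones (2 higher, 16 lower, 2 not called, adjusted p = 5.43e-06) and the unfolded protein response (1 higher, 16 lower, 1 not called, adjusted p = 7.82e-05). Oxidative stress (3 higher, 18 lower, 2 not called, adjusted p = 1.24e-05) and galactose genes (0 higher, 4 lower, 4 not called, adjusted p = 1.87e-05) were also lower. All of these held with an estimated correlation. Pyrimidine synthesis was higher and held too (5 higher, 3 lower, 2 not called, adjusted p = 0.00012), but not without chromosomes V and IX (0.092), where URA3 lies. Nitrogen catabolite repression, with 5 genes on chromosome IX, was lower (6 higher, 11 lower, 3 not called, adjusted p = 0.000593), but adjusted p = 0.255 with an estimated correlation. Sterol uptake and anaerobic cell wall genes were lower (1 higher, 6 lower, 3 not called or 2 higher and 6 lower adjusted over the list alone, adjusted p = 0.0387; adjusted p = 0.389 with an estimated correlation), TIR1 among them (-8.70 ± 0.26), a call lost without LP118 6 h replicate 3 (0.0543) and without chromosomes V and IX (0.285). Other lists, 2 higher and 2 lower, lost the call with an estimated correlation (adjusted p = 0.221 to 0.37).

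At 24 h, LP104-17 had far more expression of ribosome-building genes than LP085-Vc. NSR1 rose from 4.32 ± 0.330 to 91.1 ± 11.7 CPM (log2 fold change 4.39 ± 0.16), NOP58 by 3.72 ± 0.15, RPA49, an RNA polymerase I subunit gene, by 3.65 ± 0.14 and the ribosomal protein gene RPL8A by 2.68 ± 0.10. MDH2, cytosolic malate dehydrogenase, fell by 2.13 ± 0.08 in log2, ACS1, acetyl-CoA synthetase, by 1.72 ± 0.09, and PCK1, the gluconeogenic enzyme gene, by 1.56 ± 0.09. SPS100, a spore wall gene, fell by 3.16 ± 0.17 and the catalase gene CTT1 by 1.74 ± 0.10. Of the sterol genes, ERG6 (0.90 ± 0.07), ERG4 (0.86 ± 0.09) and ERG11 (0.72 ± 0.08) were higher and ERG9 was lower (-0.49 ± 0.08). Of 16 genes in the list from squalene to ergosterol, 11 were higher, 1 lower and 4 not called, and its call was lost with an estimated correlation (adjusted p = 0.473).

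Here 3222 genes were called, 1541 higher and 1681 lower, with 601 up and 167 down at least 2-fold. On log2(FPKM + 1) the split was 1891 higher and 1048 lower, a share of 64.3% against 47.8%, and on log2(FPKM + 0.1) it was 1894 and 1032. Ribosome biogenesis was higher in full (49 higher, 0 lower, 0 not called, adjusted p = 6.97e-62). The environmental stress response was lower (0 higher, 30 lower, 4 not called or 0 higher and 31 lower adjusted over the list alone, adjusted p = 3.24e-16). Glucose-repressed carbon metabolism was lower (2 higher, 14 lower, 2 not called or 2 higher and 15 lower adjusted over the list alone, adjusted p = 2.18e-09), and so was peroxisomal beta-oxidation (0 higher, 11 lower, 4 not called, adjusted p = 0.000108), with the carnitine acetyltransferase gene CAT2 at -1.67 ± 0.10. These 4 calls held with an estimated correlation. Ribosomal proteins were higher (132 higher, 0 lower, 6 not called or 134 higher and 0 lower adjusted over the list alone, adjusted p = 3.1e-59), but adjusted p = 0.0946 with an estimated correlation. Squalene to ergosterol (11 higher, 1 lower, 4 not called or 12 higher and 1 lower adjusted over the list alone, adjusted p = 0.0356; adjusted p = 0.473 with an estimated correlation) and sulfur and methionine (14 higher, 0 lower, 6 not called, adjusted p = 0.00188; adjusted p = 0.329 with an estimated correlation) were higher without holding. Pleiotropic drug resistance was lower (1 higher, 12 lower, 5 not called, adjusted p = 0.046; adjusted p = 0.626 with an estimated correlation), with the transporter gene SNQ2 at -1.04 ± 0.15, a call lost without LP085-Vc 24 h replicate 1 (0.0507) or LP104-17 24 h replicate 2 (0.0831). Other lists, 3 higher and 2 lower, lost the call with an estimated correlation (adjusted p = 0.224 to 0.626).

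Against LP085-Vc at 24 h, single genes of glucose uptake and glycolysis were higher in LP118, though the calls of the hexose transporter list (7 higher, 4 lower, 0 not called, adjusted p = 0.00131; adjusted p = 0.0569 with an estimated correlation) and of the glycolysis list (adjusted p = 0.0629) were lost with such an estimate. The low-affinity glucose transporter gene HXT3 was at 6864 ± 164 CPM against 53.0 ± 1.16 CPM (log2 fold change 7.02 ± 0.10) and HXT1 rose by 6.66 ± 0.15. Enolase ENO2 was up by 5.46 ± 0.14, pyruvate decarboxylase PDC1 by 4.68 ± 0.13 and hexokinase HXK2 by 4.18 ± 0.11. The glyoxylate cycle genes MLS1 and ICL1 (the latter on chromosome V) were down by 7.39 ± 0.15 and 7.29 ± 0.14 in log2. The gluconeogenesis genes PCK1 (-7.38 ± 0.12) and FBP1 (-7.18 ± 0.18) were lower too. RGI2, a respiratory growth gene on chromosome IX, was at -7.99 ± 0.23 and DPA10 at -6.55 ± 0.15.

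Of all tested genes 4761 were called, the most of any comparison, 2360 higher and 2401 lower, with 1375 up and 1242 down at least 2-fold. The median of all genes on log2(FPKM + 1) was 0.19. Glucose-repressed carbon metabolism was lower (1 higher, 16 lower, 1 not called, adjusted p = 4.09e-20). The tricarboxylic acid cycle was lower in full (0 higher, 15 lower, 0 not called, adjusted p = 3.8e-12), with citrate synthase CIT1 at -2.98 ± 0.09, and so was beta-oxidation (0 higher, 13 lower, 2 not called, adjusted p = 1.12e-06). Acetyl-CoA supply was lower (1 higher, 14 lower, 0 not called, adjusted p = 2.85e-07), with the acetyl-CoA hydrolase gene ACH1 at -4.81 ± 0.09. Galactose genes (0 higher, 8 lower, 0 not called, adjusted p = 1.12e-06) and the environmental stress response (0 higher, 34 lower, 0 not called, adjusted p = 5.25e-25) were lower as well. Ribosome biogenesis was higher (48 higher, 0 lower, 1 not called, adjusted p = 2.13e-31), and so was lysine synthesis (8 higher, 1 lower, 0 not called, adjusted p = 3.54e-05), where LYS12, on chromosome IX, rose by 3.99 ± 0.10. These 8 calls held with an estimated correlation. Glycolysis and ethanol formation was higher in full, with a median of 2.89 (17 higher, 0 lower, 0 not called, adjusted p = 3.24e-13), but adjusted p = 0.0629 with an estimated correlation. Ribosomal proteins were higher (135 higher, 0 lower, 3 not called, adjusted p = 9.98e-40; adjusted p = 0.108 with an estimated correlation). Oxidative phosphorylation was lower (1 higher, 34 lower, 0 not called, adjusted p = 7.25e-12; adjusted p = 0.108 with an estimated correlation), with RIP1, the Rieske protein gene on chromosome V, at -3.72 ± 0.10. Histidine and tryptophan synthesis was higher in full (16 higher, 0 lower, 0 not called, adjusted p = 3.52e-08; adjusted p = 0.0629 with an estimated correlation), a list that holds HIS3 and TRP1, the latter with 2 counts in LP085-Vc. Other lists, 4 higher and 2 lower, lost the call with an estimated correlation (adjusted p = 0.106 to 0.318).

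Against LP104-17 at 24 h, LP118 was again higher in genes of fermentation and lower in genes of respiration. ENO2 rose by 5.51 ± 0.14, HXT3 by 6.99 ± 0.10 and TDH3 by 3.95 ± 0.11. MLS1 (-6.64 ± 0.15), PCK1 (-5.82 ± 0.11), the lactate permease gene JEN1 (-4.78 ± 0.11) and citrate synthase CIT1 (-2.98 ± 0.09) were lower. Called genes numbered 4208, 2147 higher and 2061 lower, with 890 up and 815 down at least 2-fold.

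Glycolysis and ethanol formation was higher than in LP104-17 in full (17 higher, 0 lower, 0 not called, adjusted p = 1.41e-25). Glucose-repressed carbon metabolism was lower (1 higher, 17 lower, 0 not called, adjusted p = 6.94e-24). Oxidative phosphorylation was lower (1 higher, 34 lower, 0 not called, adjusted p = 1.18e-22), as was the tricarboxylic acid cycle (0 higher, 15 lower, 0 not called, adjusted p = 1.23e-20). So were the environmental stress response (0 higher, 34 lower, 0 not called, adjusted p = 1.01e-21) and beta-oxidation (0 higher, 12 lower, 3 not called, adjusted p = 1.59e-05). Acetyl-CoA supply (1 higher, 12 lower, 2 not called, adjusted p = 2.27e-07) and galactose genes (0 higher, 7 lower, 1 not called, adjusted p = 1.03e-07) were lower too. Higher were hexose transporters (7 higher, 4 lower, 0 not called, adjusted p = 2.05e-06) and lysine synthesis (8 higher, 0 lower, 1 not called, adjusted p = 3.13e-07). Branched-chain synthesis (12 higher, 1 lower, 0 not called, adjusted p = 2.92e-07) and ribosome biogenesis (45 higher, 1 lower, 3 not called or 46 higher and 2 lower adjusted over the list alone, adjusted p = 5.3e-10) were higher as well. All of these held with an estimated correlation. Ribosomal proteins were higher (132 higher, 0 lower, 6 not called, adjusted p = 1.3e-19), but adjusted p = 0.227 with an estimated correlation. Thiamine synthesis was higher (8 higher, 1 lower, 5 not called, adjusted p = 0.0227; adjusted p = 0.0628 with an estimated correlation), with THI4 at 3.12 ± 0.11. Nitrogen catabolite repression was lower (3 higher, 16 lower, 1 not called, adjusted p = 0.000355; adjusted p = 0.171 with an estimated correlation), with the proline permease gene PUT4 at -3.96 ± 0.10. Other lists, 4 higher and 1 lower, lost the call with an estimated correlation (adjusted p = 0.0544 to 0.133).

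**Figure D2:**
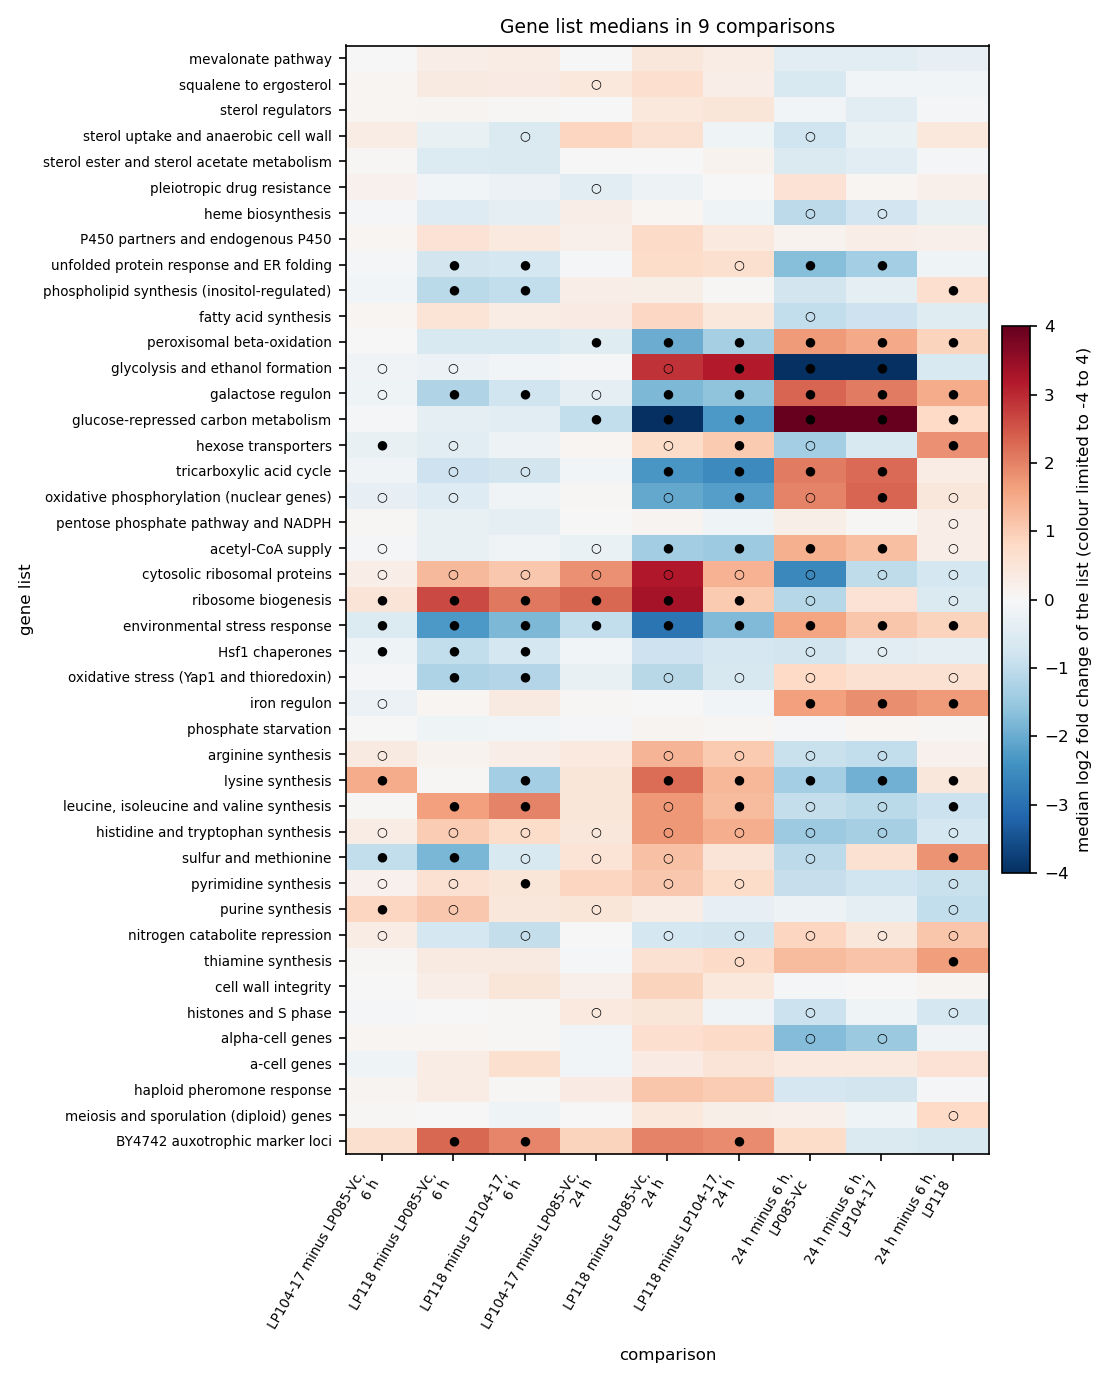
Median log2 fold change of each tested gene list (lines) in each comparison (columns), coloured from -4 to 4; a filled dot marks a list called by camera and with an estimated correlation, an open dot one called by camera only. Ribosome biogenesis is called higher in LP104-17 and LP118 than in LP085-Vc at both times, and glycolysis is called lower over time in LP085-Vc and LP104-17.

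Most genes called in LP104-17 against LP085-Vc were called in the same direction in LP118. At 6 h both had 305 genes higher and 311 lower, which is 85.9% and 88.1% of those called in LP104-17, against 114 and 119 for independent lists, and 26 and 20 were opposite. At 24 h 1342 were higher and 1372 lower in both (87.1% and 81.6%, against 593 and 658), with 63 and 126 opposite. At 6 h the shared calls in both directions numbered 616, and 971 without LP104-17 6 h replicate 2. The fold changes correlated across genes at 0.584 at 6 h and 0.734 at 24 h, against 0.474 and 0.498 for simulated unchanged groups that shared the controls. Sharing controls gives such correlations by construction, whatever the size of the noise, so they do not measure the part due to the controls. The covariance was 0.266 at 6 h and 0.913 at 24 h, against 0.0227 and 0.0253 in the simulations. The simulated groups shared at most 0 calls in 20 simulations at each time. The simulations held no structure common to the genes of a library. Genes are not independent replicates. Both comparisons use the same 3 LP085-Vc libraries, which are too few to split, so part of the excess may come from them.

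Over time in LP085-Vc, genes of glycolysis and ethanol formation fell, and single genes of gluconeogenesis, the glyoxylate cycle and respiratory growth rose. MLS1 rose by 9.66 ± 0.17, PCK1 by 9.17 ± 0.13, the succinate-fumarate carrier gene SFC1 by 9.57 ± 0.20, RGI2 by 8.97 ± 0.25 and DPA10 by 10.78 ± 0.20. ENO2 fell from 14750 ± 2070 to 57.1 ± 9.33 CPM (-8.01 ± 0.16), with TDH2 at -6.36 ± 0.12 and HXT3 at -5.23 ± 0.09. The ribosomal protein gene RPS2 (-3.65 ± 0.11) and the folding gene KAR2 (-2.56 ± 0.09) fell, and iron regulon genes rose, FIT3 by 6.30 ± 0.17 and the heme oxygenase gene HMX1 by 5.51 ± 0.15. In all 4670 genes were called, 2324 higher and 2346 lower, with 1050 up and 1245 down at least 2-fold.

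Glucose-repressed carbon metabolism rose in LP085-Vc with a median of 5.09 (15 higher, 3 lower, 0 not called, adjusted p = 1.18e-25), and glycolysis fell in full (0 higher, 17 lower, 0 not called, adjusted p = 1.04e-23). The tricarboxylic acid cycle rose (14 higher, 1 lower, 0 not called, adjusted p = 6.45e-10), and so did beta-oxidation (14 higher, 1 lower, 0 not called, adjusted p = 1.77e-09). Galactose genes (8 higher, 0 lower, 0 not called, adjusted p = 9.8e-08) and acetyl-CoA supply (11 higher, 1 lower, 3 not called, adjusted p = 4.97e-08) rose, with acetyl-CoA synthetase ACS1 at 6.22 ± 0.12. Upward too went the environmental stress response (25 higher, 4 lower, 5 not called, adjusted p = 6.45e-10) and the iron regulon (18 higher, 0 lower, 2 not called or 18 higher and 1 lower adjusted over the list alone, adjusted p = 7.97e-11). The unfolded protein response (2 higher, 15 lower, 1 not called, adjusted p = 1.75e-06) and lysine synthesis (0 higher, 7 lower, 2 not called, adjusted p = 0.000974) fell. These calls held with an estimated correlation. Oxidative phosphorylation rose (34 higher, 1 lower, 0 not called, adjusted p = 5.45e-13), but adjusted p = 0.0769 with an estimated correlation. Ribosomal proteins (0 higher, 136 lower, 2 not called, adjusted p = 1.95e-32; adjusted p = 0.106 with an estimated correlation) and ribosome biogenesis (3 higher, 38 lower, 8 not called or 4 higher and 38 lower adjusted over the list alone, adjusted p = 3.9e-06; adjusted p = 0.112 with an estimated correlation) fell without holding. Fatty acid synthesis fell (1 higher, 8 lower, 3 not called, adjusted p = 0.0221; adjusted p = 0.0769 with an estimated correlation), with the elongase gene ELO3 at -4.53 ± 0.14 but the desaturase gene OLE1 at 3.25 ± 0.09. Heme biosynthesis (1 higher, 6 lower, 1 not called, adjusted p = 0.0221; adjusted p = 0.112 with an estimated correlation) and alpha-cell genes (0 higher, 5 lower, 0 not called, adjusted p = 0.00905; adjusted p = 0.0769 with an estimated correlation) fell. Sterol uptake and anaerobic cell wall genes fell (3 higher, 7 lower, 0 not called, adjusted p = 0.0394; adjusted p = 0.292 with an estimated correlation), a call lost without LP085-Vc 24 h replicate 1 (0.0588). Other lists, 2 higher and 7 lower, lost the call with an estimated correlation (adjusted p = 0.0769 to 0.246).

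LP104-17 changed over time much as LP085-Vc did. MLS1 rose by 8.65 ± 0.17, PCK1 by 7.41 ± 0.12, RGI2 by 8.88 ± 0.27 and FIT3 by 7.03 ± 0.18, while ENO2 fell by 7.96 ± 0.16 and LYS9 by 4.86 ± 0.09 in log2. Called genes numbered 4347, 2160 higher and 2187 lower, with 883 up and 908 down at least 2-fold. Of the genes that changed at least 2-fold in LP085-Vc, 989 of the higher (94.2%) and 1082 of the lower (86.9%) were called the same way in LP104-17, and 0 and 44 the opposite way. The changes of both strains correlated across 6131 genes at r = 0.889 (Spearman's rho 0.856) with a slope of 0.749.

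Glucose-repressed carbon metabolism rose in LP104-17 too (15 higher, 3 lower, 0 not called, adjusted p = 6.32e-25). The tricarboxylic acid cycle (14 higher, 1 lower, 0 not called, adjusted p = 2.44e-13) and oxidative phosphorylation (34 higher, 1 lower, 0 not called, adjusted p = 2.14e-23) rose, with the NADH dehydrogenase gene NDE1 at 5.57 ± 0.11. Beta-oxidation (14 higher, 1 lower, 0 not called, adjusted p = 1.85e-06) and galactose genes (8 higher, 0 lower, 0 not called, adjusted p = 1.27e-08) rose. So did acetyl-CoA supply (10 higher, 3 lower, 2 not called or 11 higher and 3 lower adjusted over the list alone, adjusted p = 1.68e-07) and the iron regulon (18 higher, 0 lower, 2 not called, adjusted p = 2.62e-19). The environmental stress response rose (22 higher, 8 lower, 4 not called or 22 higher and 9 lower adjusted over the list alone, adjusted p = 9.85e-08). Glycolysis fell in full (0 higher, 17 lower, 0 not called, adjusted p = 1.47e-31). The unfolded protein response (1 higher, 17 lower, 0 not called, adjusted p = 4.83e-09) and lysine synthesis (0 higher, 7 lower, 2 not called, adjusted p = 3.81e-10) fell. These calls held with an estimated correlation. Ribosomal proteins fell (2 higher, 126 lower, 10 not called, adjusted p = 4.55e-10), but adjusted p = 0.448 with an estimated correlation. Other lists, 1 higher and 6 lower, lost the call with an estimated correlation (adjusted p = 0.0717 to 0.265).

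LP118 shared part of the change over time of the other strains. As in both, FIT3 rose, from 65.6 ± 8.82 to 4895 ± 171 CPM (log2 fold change 6.22 ± 0.17), HSP26 rose by 5.55 ± 0.11 and PCK1 by 2.05 ± 0.12, while ENO2 fell by 2.35 ± 0.12 in log2 and LEU1 by 2.95 ± 0.10. HXT4 rose (4.88 ± 0.12) but fell in LP085-Vc (-5.53 ± 0.14), and its change was higher than in LP104-17 by 8.61 ± 0.18. NCE103 fell (-2.12 ± 0.10), and its change was lower than in LP104-17 (-5.81 ± 0.15). The sulfate permease gene SUL2 (2.97 ± 0.15), MET17 (2.75 ± 0.14), INO1 (4.23 ± 0.08) and THI4 (3.30 ± 0.12) rose in LP118. Calls numbered 3502, 1630 higher and 1872 lower, with 590 up and 234 down at least 2-fold. On log2(FPKM + 1) the split was 2179 higher and 1210 lower, a share of 64.3% against 46.5%, with a median of all genes of 0.13, and on log2(FPKM + 0.1) it was 2167 and 1196. Of the genes changed at least 2-fold in LP085-Vc, 705 of the higher (67.1%) and 807 of the lower (64.8%) were called the same way in LP118, and 36 (3.43%) and 109 (8.76%) the opposite way. Their median change was 1.64 in LP085-Vc, 1.37 in LP104-17 and 0.624 in LP118 for the higher, and -1.74, -1.18 and -0.543 for the lower. The time changes of LP118 correlated with those of LP085-Vc at r = 0.524 (rho 0.575, slope 0.294) and with those of LP104-17 at r = 0.535 (rho 0.535, slope 0.356).

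In LP118 the iron regulon (17 higher, 0 lower, 3 not called, adjusted p = 8.73e-25) and sulfur and methionine (18 higher, 0 lower, 2 not called, adjusted p = 1.68e-18) rose over time. Hexose transporters rose (8 higher, 1 lower, 2 not called, adjusted p = 9.37e-11). Phospholipid synthesis (10 higher, 1 lower, 2 not called or 11 higher and 1 lower adjusted over the list alone, adjusted p = 2.76e-07) and thiamine synthesis (11 higher, 1 lower, 2 not called, adjusted p = 9.93e-06) rose. Galactose genes (8 higher, 0 lower, 0 not called, adjusted p = 4.14e-12) and the environmental stress response (29 higher, 0 lower, 5 not called, adjusted p = 2.94e-18) rose too. Glucose-repressed carbon metabolism rose with a median of 0.81 (14 higher, 3 lower, 1 not called, adjusted p = 1.32e-05). Beta-oxidation (11 higher, 0 lower, 4 not called, adjusted p = 8e-04) and lysine synthesis (7 higher, 0 lower, 2 not called or 7 higher and 1 lower adjusted over the list alone, adjusted p = 0.000405) rose. Branched-chain synthesis fell in full (0 higher, 13 lower, 0 not called, adjusted p = 1.51e-10). These calls held with an estimated correlation. Ribosomal proteins fell (2 higher, 119 lower, 17 not called or 2 higher and 121 lower adjusted over the list alone, adjusted p = 1.24e-10), but adjusted p = 0.361 with an estimated correlation. Ribosome biogenesis (0 higher, 47 lower, 2 not called, adjusted p = 1.6e-08; adjusted p = 0.0583 with an estimated correlation) and purine synthesis (0 higher, 14 lower, 2 not called, adjusted p = 3.31e-09; adjusted p = 0.0576 with an estimated correlation) fell without holding. Other lists, 6 higher and 3 lower, lost the call with an estimated correlation (adjusted p = 0.0576 to 0.434).

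**Figure D3:**
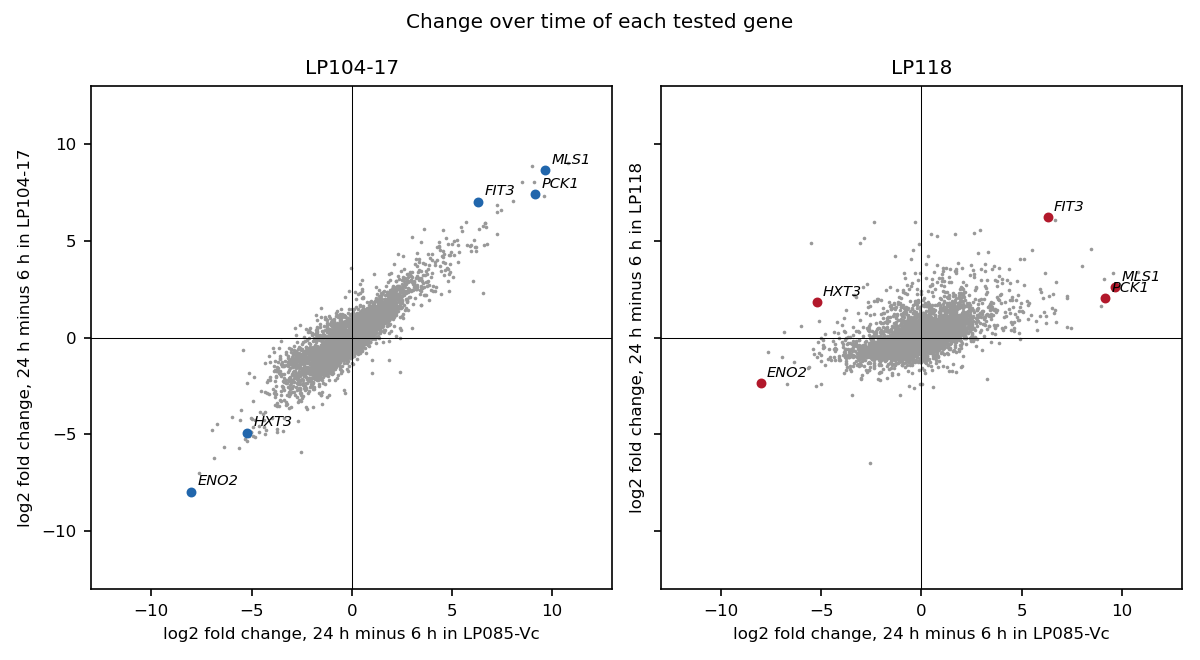
Each point is 1 of 6131 tested genes, with its log2 fold change from 6 h to 24 h in LP085-Vc on the horizontal axes and in LP104-17 (left) or LP118 (right) on the vertical axes, and 5 genes are marked. The changes of LP085-Vc correlate at r = 0.889 with those of LP104-17 and at r = 0.524 with those of LP118.

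The strains differed in their change over time for 2032 genes between LP104-17 and LP085-Vc (1092 higher, 940 lower), 3687 between LP118 and LP085-Vc (1872 and 1815) and 3056 between LP118 and LP104-17 (1504 and 1552). Against LP085-Vc, the change in LP118 was higher for HXT4 (10.41 ± 0.19) and TDH1 (8.01 ± 0.16). Both of these genes rose over time in LP118 (4.88 ± 0.12 and 5.16 ± 0.12). ENO2 fell less in LP118 (-2.35 ± 0.12) than in LP085-Vc (-8.01 ± 0.16). The single gluconeogenesis gene PCK1 rose less in LP118 than in LP085-Vc (difference -7.12 ± 0.17). The change of NSR1 was higher in LP104-17 than in LP085-Vc by 3.26 ± 0.21 and that of RPA49 by 3.15 ± 0.17. On log2(FPKM + 1) the splits were 1284 higher and 537 lower (70.5% against 53.7%), 2382 and 1201 (66.5% against 50.8%) and 1846 and 1175 (61.1% against 49.2%), with medians of all genes of 0.24 and 0.13 for LP118 against LP085-Vc and against LP104-17. With 0.1 in place of 1 they were 1276 and 522, 2373 and 1183, and 1835 and 1150.

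Between LP104-17 and LP085-Vc the change over time was higher for ribosome biogenesis (48 higher, 0 lower, 1 not called, adjusted p = 3.91e-50) and sulfur and methionine (18 higher, 0 lower, 2 not called, adjusted p = 4.46e-29). It was lower for glucose-repressed carbon metabolism (2 higher, 12 lower, 4 not called, adjusted p = 1.48e-07). Lysine synthesis (0 higher, 7 lower, 2 not called, adjusted p = 5.16e-06) and beta-oxidation (0 higher, 8 lower, 7 not called or 0 higher and 9 lower adjusted over the list alone, adjusted p = 0.000119) were lower too. Between LP118 and LP085-Vc it was higher for glycolysis (17 higher, 0 lower, 0 not called, adjusted p = 1.57e-36) and hexose transporters (8 higher, 2 lower, 1 not called, adjusted p = 7.94e-15). Sulfur and methionine (18 higher, 0 lower, 2 not called, adjusted p = 1.71e-22) and lysine synthesis (7 higher, 0 lower, 2 not called, adjusted p = 1.99e-10) were higher, with LYS9 at 5.16 ± 0.12. It was higher as well for the unfolded protein response (15 higher, 1 lower, 2 not called, adjusted p = 1.94e-07) and phospholipid synthesis (10 higher, 1 lower, 2 not called, adjusted p = 6.12e-09). Lower were glucose-repressed carbon metabolism (2 higher, 16 lower, 0 not called, adjusted p = 4.2e-21) and the tricarboxylic acid cycle (0 higher, 13 lower, 2 not called, adjusted p = 1.22e-10). Beta-oxidation (0 higher, 9 lower, 6 not called, adjusted p = 9.21e-05) and acetyl-CoA supply (1 higher, 11 lower, 3 not called, adjusted p = 1.24e-06) were lower. Between LP118 and LP104-17 it was higher for glycolysis (17 higher, 0 lower, 0 not called, adjusted p = 4.56e-48) and lysine synthesis (7 higher, 0 lower, 2 not called or 8 higher and 0 lower adjusted over the list alone, adjusted p = 2.07e-25). Hexose transporters (7 higher, 2 lower, 2 not called or 7 higher and 3 lower adjusted over the list alone, adjusted p = 1.14e-13), the unfolded protein response (16 higher, 1 lower, 1 not called, adjusted p = 2.48e-10) and phospholipid synthesis (10 higher, 1 lower, 2 not called, adjusted p = 1.13e-08) were higher. The respiratory lists were lower, oxidative phosphorylation (1 higher, 33 lower, 1 not called, adjusted p = 1.75e-23) and the tricarboxylic acid cycle (0 higher, 13 lower, 2 not called, adjusted p = 1.66e-13). Glucose-repressed carbon metabolism (2 higher, 15 lower, 1 not called, adjusted p = 3.43e-16) and ribosome biogenesis (0 higher, 37 lower, 12 not called or 0 higher and 39 lower adjusted over the list alone, adjusted p = 2.51e-11) were lower. All these calls held with an estimated correlation. Further lists lost the call with an estimated correlation: 8 higher and 5 lower between LP104-17 and LP085-Vc (adjusted p = 0.0699 to 0.588), 7 and 2 between LP118 and LP085-Vc (0.119 to 0.365) and 6 and 4 between LP118 and LP104-17 (0.0636 to 0.842).

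Genes of the sterol pathway differed in direction from one another. ERG1 (squalene epoxidase) fell over time from 10910 ± 1090 to 813 ± 19.9 CPM in LP085-Vc (-3.75 ± 0.10) and by 3.55 ± 0.10 in log2 in LP104-17. In LP118 it fell from 9142 ± 320 to 3931 ± 538 CPM, and its change differed from that of LP085-Vc by 2.53 ± 0.13 in log2. ERG6, the sterol C-24 methyltransferase gene, was lower in LP118 than in LP085-Vc at 6 h (-1.74 ± 0.08) and at 24 h (-1.09 ± 0.08), and at 24 h was 497 ± 21.0, 929 ± 27.1 and 234 ± 6.60 CPM in LP085-Vc, LP104-17 and LP118. ERG11, the lanosterol demethylase P450 gene, was higher in LP118 at 6 h (0.60 ± 0.08) and at 24 h (1.32 ± 0.08), and so were ERG7 (0.94 ± 0.09 and 1.12 ± 0.09) and ERG2 (0.92 ± 0.11 and 1.59 ± 0.12). ERG28, on chromosome V, was lower in LP118 at 6 h (-1.91 ± 0.13), and squalene synthase ERG9 was lower at 24 h in LP104-17 (-0.49 ± 0.08) and LP118 (-1.19 ± 0.08). Against LP085-Vc at 6 h, no tested gene of the 9 in the mevalonate pathway was called in LP104-17, and in LP118 5 were higher and 1 lower, ERG13 at 1.16 ± 0.10 and MVD1 at 1.03 ± 0.09 among the higher. Of the 5, HMG1 (0.39 ± 0.14) lost its call with the length trend removed (-0.0046, adjusted p = 0.977), without LP118 6 h replicate 1 (0.34, adjusted p = 0.0651) and on log2(FPKM + 1) (0.33, adjusted p = 0.0643) and log2(FPKM + 0.1) (0.33, adjusted p = 0.0667). The mevalonate list was called in no comparison (lowest camera adjusted p = 0.0899, in LP118 over time, 0 higher and 6 lower).

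**Figure D4:**
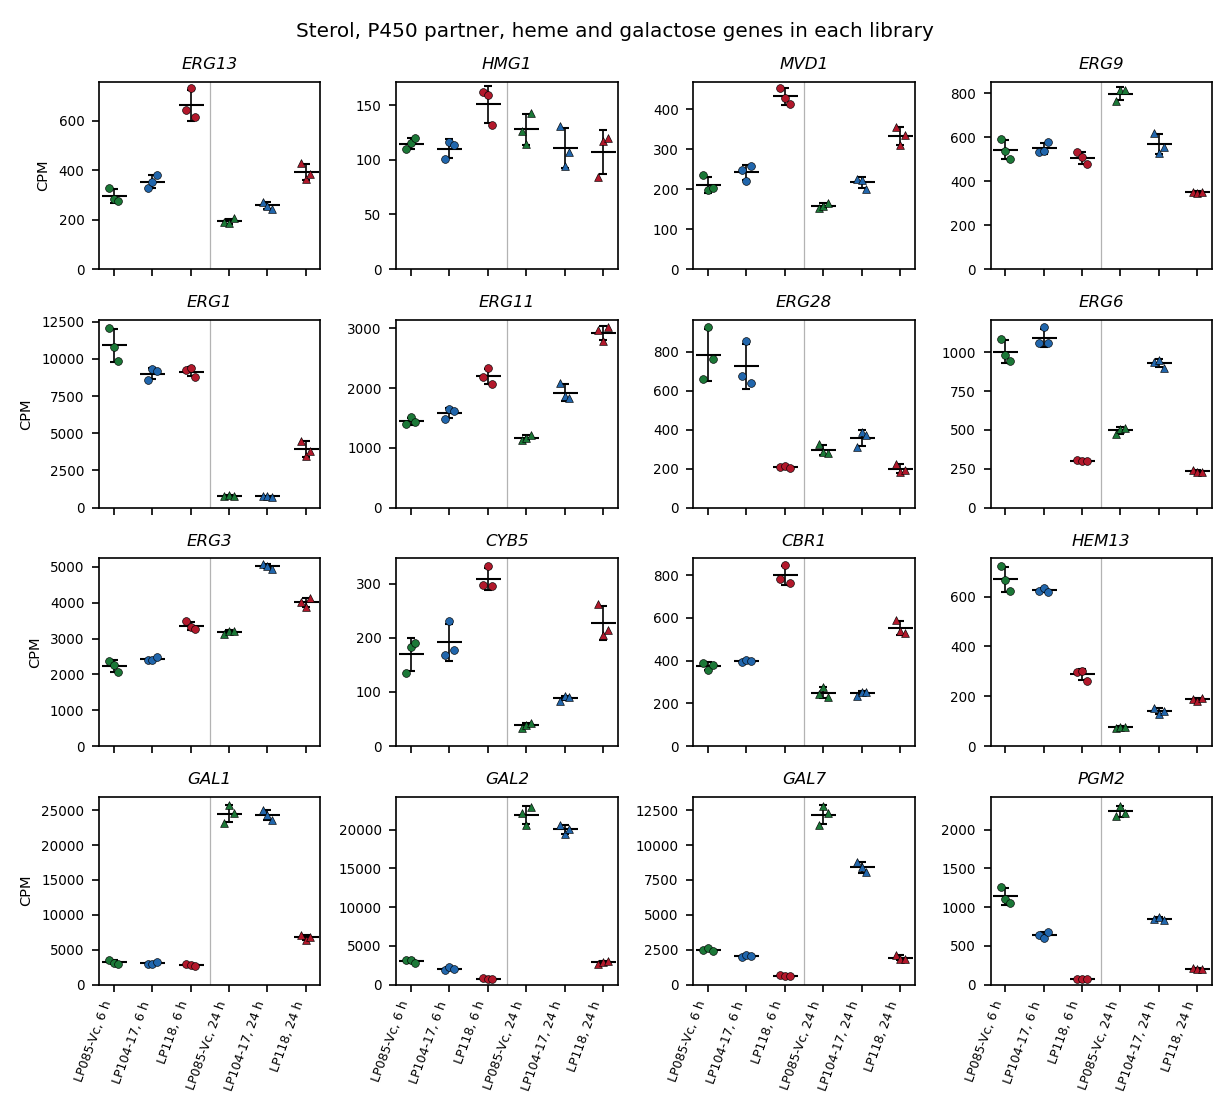
CPM of 16 genes of the sterol pathway, its P450 partners, heme and galactose use in the 6 groups; points are libraries and bars are the mean ± SD of 3. ERG1 falls at 24 h in LP085-Vc and LP104-17 more than in LP118, and ERG6 is lowest in LP118.

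P450 partner genes differed in direction in LP118. Cytochrome b5 (CYB5) was at 227 ± 31.0 CPM at 24 h against 38.5 ± 4.29 in LP085-Vc (2.56 ± 0.15) and 89.0 ± 4.31 in LP104-17 (1.21 ± 0.15 over LP085-Vc). Cytochrome b5 reductase CBR1, on chromosome IX, was higher at 6 h (1.09 ± 0.08) and 24 h (1.14 ± 0.08), and the P450 reductase gene NCP1 at 6 h (0.53 ± 0.13) and 24 h (0.47 ± 0.13). MCR1, the mitochondrial cytochrome b5 reductase gene, was lower than in LP085-Vc at 6 h (-1.23 ± 0.10) and 24 h (-2.31 ± 0.10), and so was the heme-binding protein gene DAP1 (-0.90 ± 0.16 and -1.18 ± 0.15). Heme genes differed in direction: HEM13 was lower in LP118 than in LP085-Vc at 6 h (-1.22 ± 0.09) and higher at 24 h (1.31 ± 0.09), HEM3 was higher at both times (0.66 ± 0.12 and 1.53 ± 0.13) and HEM14, on chromosome V, lower at both (-1.42 ± 0.08 and -1.14 ± 0.08). Of the drug transporter genes PDR5 was higher in LP118 than in LP104-17 at 24 h (1.29 ± 0.15), and PDR10 lower (-1.68 ± 0.12).

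Galactose genes were expressed in all groups of these glucose cultures. GAL1 (galactokinase) was at 3182 ± 268, 3069 ± 207 and 2771 ± 123 CPM at 6 h in LP085-Vc, LP104-17 and LP118, and at 24520 ± 1240, 24300 ± 742 and 6792 ± 359 CPM at 24 h. The galactose permease gene GAL2 was at 21900 ± 1200, 20040 ± 551 and 2867 ± 187 CPM at 24 h. The repressor gene GAL80 had 24 and 5 counts over the LP085-Vc libraries at 6 h and 24 h, 13 and 1 in LP104-17, and 9 and 6 in LP118. GAL80 and ATF2, an alcohol acetyltransferase gene with 0 counts in all 18 libraries, were too low to test. Among alpha-cell genes, the pheromone gene MF(ALPHA)1 was higher at 24 h than in LP085-Vc in LP104-17 (1.89 ± 0.12) and LP118 (2.24 ± 0.12). The a-cell gene BAR1 was higher in LP118 at 6 h (1.88 ± 0.24) and lies on chromosome IX.

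In LP118 the genes of chromosome V were lower and those of chromosome IX higher than in both other strains. The median log2 fold change of 276 genes of chromosome V was -0.995 against LP085-Vc and -0.978 against LP104-17 at 6 h, and -1.08 and -0.981 at 24 h. For 205 genes of chromosome IX it was 0.878, 0.923, 0.952 and 1.02. The other 5217 placed genes had medians of -0.0316, -0.0215, 0.00925 and 0.0321. Between LP104-17 and LP085-Vc the medians of V and IX were -0.00179 and -0.0015 at 6 h, and -0.0379 and -0.0887 at 24 h. Called lower were 218, 228, 192 and 210 genes of V, and called higher 165, 167, 147 and 161 of IX, in the same order. All 12 bins of V and all 9 of IX had medians beyond 0.5 in that direction. In a two-sided permutation test of LP118 libraries against the others within each time, both chromosomes reached the smallest possible p, 0.000142 (adjusted over chromosomes 0.000567). So did VI and XIV, with medians of -0.135 and -0.11, and 0.0515 and 0.0796, at 6 h and 24 h. Values were centred on the LP085-Vc and LP104-17 libraries before the regrouping. The centring was not repeated for each regrouping, so the p-values of this test are not exact and no conclusion rests on them. Only I, III and XV had an adjusted p above 0.05 in this permutation test. X, with shifts of only 0.0133 and 0.0568, had 0.00142, so this test does not set V and IX apart from the other chromosomes. These tests were chosen after the values were seen.

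**Figure D5:**
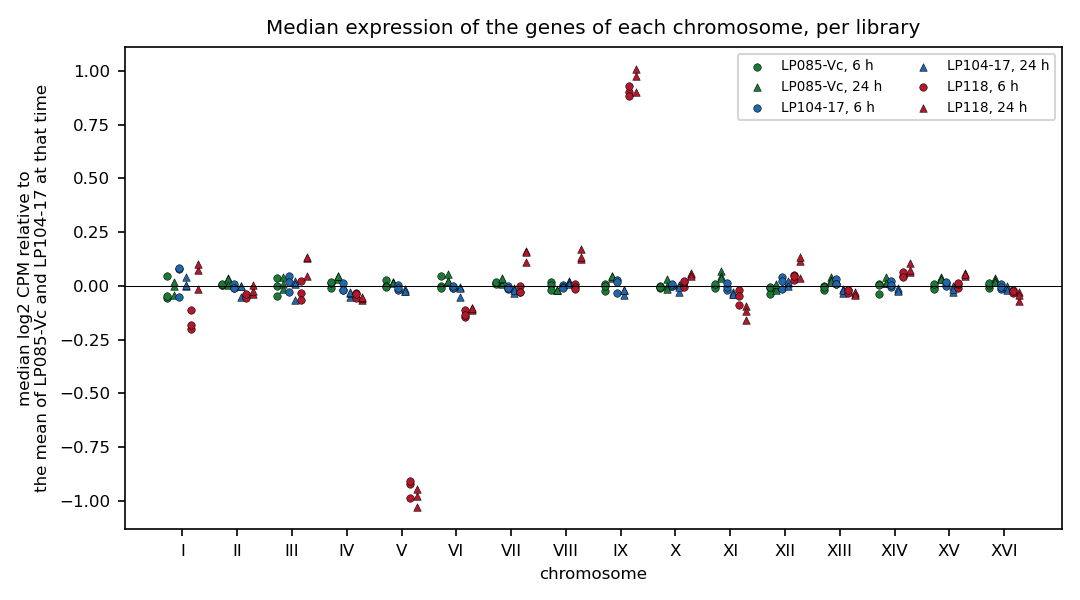
Each point is a library's median log2 CPM of the genes of a chromosome, relative to the mean of the LP085-Vc and LP104-17 libraries at that time. In LP118 chromosome V lies near -1 and chromosome IX near 1 at both times, and the other chromosomes lie near 0.

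Of the lists for cell function, sterol regulators (lowest camera adjusted p over the 9 comparisons 0.476), sterol ester and acetate metabolism (0.174), P450 partners (0.483), phosphate starvation (0.184), cell wall integrity (0.158), a-cell genes (0.358) and haploid pheromone response (0.135) were called in no comparison between strains or times.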

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

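The differences between strains in the change over time were tested as planned, and every test of an explanation below was chosen after the result was seen. A value is given here where such a difference passed its test in edgeR, or where data outside the comparisons held a signal.

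The change from 6 h to 24 h differed between LP104-17 and LP085-Vc for 2032 genes. Of 100 splits of the libraries within each time, 7 gave as many, the real one included, with 3054 in the highest other split, so chance is not excluded by that share. The other 6 all held the strains whole at one time or both, which carries a strain difference into the interaction, so they say little about chance. The 80 splits that mixed the strains at both times gave at most 357. Between LP118 and LP085-Vc the count was 3687 and between LP118 and LP104-17 it was 3056. For each of these, 2 of 100 splits gave as many, the real one included, and the highest other splits gave 4796 and 4373. Those highest splits exchanged the strains at only one time, which turns the strain difference into the interaction. The highest of the rest gave 3684 and 2758. Because splits that hold the strains whole at one time carry a strain difference, that share cannot decide on chance here either. The 80 splits that mixed the strains at both times gave 0 genes in both cases.

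The largest log2 differences between LP104-17 and LP085-Vc in the change over time were 3.645 for HXT6, 3.349 for HAS1, 3.305 for UTP13, 3.259 for NSR1 and 3.186 for NOP58. In the other direction they were -3.149 for SPS100, -2.504 for MDH2, -2.449 for ADY2, -2.254 for SFC1 and -2.212 for PHM7. HXT6 and HXT7 are near copies, and the value of HXT6 may mix their reads (95.1% of its windows are repeated).

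Between LP118 and LP085-Vc the highest values were 10.41 for HXT4, 8.01 for TDH1, 7.925 for TPO2, 7.132 for ANB1, a gene repressed by oxygen, and 7.048 for HXT3. The lowest were -7.399 for DPA10, -7.32 for RGI2, -7.123 for PCK1, -7.037 for MLS1 and -6.935 for FBP1. Between LP118 and LP104-17 the values were 8.614 for HXT4, 8.122 for TDH1, 6.995 for TPO2, 6.731 for HXT3 and 6.491 for ANB1. In the other direction they were -7.231 for RGI2, -6.063 for FBP1, -6.029 for MLS1, -5.808 for NCE103 and -5.639 for DPA10.

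LP118 at 24 h showed little of the change over time of LP085-Vc. Exchanged time labels in LP118 are excluded, since they would make the changes of LP118 and LP085-Vc run in opposite directions, and they correlated at r = 0.524 across genes. Dosage of chromosomes V and IX acting on their own genes alone does not account for the pattern, which was also present in the other genes. Across the 5650 genes not placed on V or IX, the time change of LP085-Vc and the difference of LP118 from LP104-17 at 24 h correlated at r = -0.755. Over all tested genes it was -0.717. Genes with no matched position stayed among the 5650. Effects of that dosage on genes of other chromosomes were not tested and remain open. An earlier point of the same course may underlie the pattern, because 67.1% of the genes higher over time in LP085-Vc were also called higher in LP118, with a median of 0.624 against 1.64, and 3.43% lower. Of the genes lower over time, 64.8% were called lower in LP118 and 8.76% higher. Some changes ran the other way: lysine synthesis fell in LP085-Vc but rose in LP118, as did HXT4 (-5.53 and 4.88). Growth and glucose were not analysed here, so a slower culture and a strain that regulates these genes otherwise remain open.

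The denominators of the deposited FPKM values exceeded the sums of gene counts, a part of the data that no comparison used. The part outside the gene counts was 3.2% ± 0.28 (SD, n = 3) of the denominator in LP085-Vc at 6 h and 0.21% ± 0.0062 at 24 h. In LP104-17 it was 3.61% ± 0.058 and 0.426% ± 0.0032, and in LP118 3.32% ± 0.092 and 1.76% ± 0.083. Which reads it holds is not given in the sources used here.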

How the results depend on the processing

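Settings named as added here were chosen after seeing the data: removing the length trend, leaving out chromosomes V and IX, and every alternative for correlations and for single libraries left out of lists and overlaps. Of 1507 gene values refitted 24556 times, 491 refits ended the call and 2 reversed the direction. Of 229 list calls refitted 3084 times, 217 refits ended the call and 1 reversed it, 120 of them with an estimated correlation. For 56 summary values there were 912 refits, and 54 of these refits moved a value.

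Between 99.1% and 100% of called genes were kept by DESeq2, 97.7% to 99.7% with RLE, 98% to 99.9% without a filter, 92.3% to 98.9% with the length trend removed (10 called in the opposite direction in LP118 against LP085-Vc at 6 h, and 0 under every other setting), and 79.8% to 96.2% on log2(FPKM + 1). In fits of only the groups compared 48% to 98.3% were kept, and 66.4% to 95.7% with a library left out.

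LP104-17 against LP085-Vc at 6 h moved most. Only the groups compared gave 344 genes (165 higher, 179 lower), from a fit with fewer samples. With each library left out in turn the counts ran from 485 to 1206 in all, 241 to 608 higher and 237 to 598 lower. The highest count came without LP104-17 6 h replicate 2. Against the other libraries of its group, that library's differences followed coding length with rho -0.582, against 0.379 and 0.491 for replicates 1 and 3. Whether this trend is the cause was not tested.

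On log2(FPKM + 1) and log2(FPKM + 0.1) the lower calls were 1050 and 1034 for LP104-17 against LP085-Vc at 24 h (1681 in edgeR), 1212 and 1198 for LP118 over time (1872), 537 and 522 for the interaction of LP104-17 with LP085-Vc (940), and 1205 and 1185 for that of LP118 with LP085-Vc (1815). These counts cover genes with an FPKM of at least 1 in 3 libraries, and the splits printed beside the comparisons only those also tested in edgeR. The FPKM denominators hold reads outside the gene counts, in shares that differ between groups. At 24 h that share was 0.21% in LP085-Vc and 0.426% in LP104-17. The median log2 fold change between them was -0.052 in edgeR and 0.087 on log2(FPKM + 1). For this comparison the small shares argue against the outside reads as the cause. In the other comparisons this was not tested. The FPKM fits used no TMM scaling, which by construction raises the fold changes of a group with higher TMM factors. At 24 h these factors ran from 0.914 to 0.929 in LP085-Vc, 1.01 to 1.03 in LP104-17 and 1.04 to 1.11 in LP118. In LP118 at 6 h they ran from 0.930 to 0.980. The direction is that of the fewer lower calls given here, and how much of the shift it makes up was not tested.

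With an estimated correlation, 7, 10, 11, 4, 8 and 13 lists were called in the 6 comparisons between strains (LP104-17 and LP118 against LP085-Vc, then LP118 against LP104-17, at 6 h and then at 24 h), 10, 11 and 11 over time in LP085-Vc, LP104-17 and LP118, and 5, 10 and 9 in the interactions. With camera's preset these were 17, 18, 17, 13, 19, 21, 26, 19, 23, 18, 19 and 19. By its construction the estimate raises the variance of a list whose genes move together. From the second comparison on, fry called 40, 38, 34, 42, 39, 41, 42, 39, 31, 35 and 32, by its construction without comparison to other genes.

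Without chromosomes V and IX, pyrimidine synthesis turned upward in LP104-17 against LP085-Vc at 6 h (adjusted p = 0.00448, 0.043 with them), because URA3 lies on V. With the length trend removed, HMG1 in LP118 against LP085-Vc at 6 h went from 0.39 to -0.0046 (adjusted p = 0.977) and PDR5 from 0.40 to -0.15 (adjusted p = 0.0782), and the cause was not tested further.

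At 2-fold or more the shared calls against LP085-Vc fell from 616 to 55 at 6 h and from 2714 to 706 at 24 h, by construction. With libraries left out they ran from 415 to 971 (without LP104-17 6 h replicate 2) and from 2427 to 2727. The correlation of LP104-17 minus LP085-Vc between times, 0.493, became 0.391 without a filter, 0.39 on log2(FPKM + 0.1) and 0.387 to 0.499 with libraries left out. That of LP118 minus LP085-Vc, 0.617, became 0.58 and 0.594, and that of LP118 minus LP104-17, 0.496, became 0.467 without a filter and 0.436 without V and IX. Between time changes, LP104-17 with LP085-Vc (0.889) gave 0.857 without a filter and 0.858 to 0.889 with libraries left out. LP118 with LP085-Vc (0.524) gave 0.479 and 0.493, and with LP104-17 (0.535) 0.5, 0.516 and 0.525 to 0.535. The causes were not tested.

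The replicate number as a block kept 93.2% to 99.5% of called genes. The numbers do not pair the libraries: of 15 pairs of groups, 0 had all matching correlations above 0.1, and 5 of 18 libraries matched their own number best.

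Splits of 3 libraries against 3 number 10, too few for a share under 0.05. The real counts 4049, 3586, 3222, 4761, 4208, 4670, 4347 and 3502 stood beside highest others of 0 or 1, and the real split was the 1 that reached them. In LP104-17 against LP085-Vc at 6 h, the real count of 708 stood beside 1302 in a split across the strains.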

Other observations

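Every test in this part was chosen after the result was seen.

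Genes of chromosome V were lower and genes of chromosome IX higher in LP118 than in both other strains, by a median fold of 0.502 to 0.508 for V and 1.84 to 1.9 for IX at 6 h. The 68 genes of V that changed by less than 0.5 in log2 from 6 h to 24 h in both other strains argue against culture stage. Their median log2 fold change was -1.05 (quartiles -1.32 and -0.764) in LP118 against LP104-17 at 24 h. Culture stage is not excluded, since genes that change only between these times could not be set aside. Sequence variants that lower read matching are excluded for IX, whose genes had a median of 0.878 against LP085-Vc at 6 h (quartiles 0.437 and 1.39), although 17 of 205 were called lower. For V, every bin lay at or below -0.638 against both other strains at both times, whereas such variants would leave some bins near 0. This argues against such variants as the cause over all of V. They are not excluded, since its bins lay up to 0.357 from its median against LP085-Vc at 6 h and no reads were used here. A change in copy number may be the cause, since the smallest absolute median of a bin of V or IX was 0.57. Bins of other chromosomes also passed 0.5, up to 0.871 against LP085-Vc at 6 h and 1.11 at 24 h, where 12 of 218 lay below -0.5 and 17 above 0.5. A haploid cannot hold less than 1 copy of V, so this would also need more than 1 genome copy or a mixed population, and DNA was not analysed here.

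A split of the 6 h libraries of LP085-Vc and LP104-17 across the strains called more genes than the strains did. LP085-Vc replicate 1 with LP104-17 replicates 1 and 3, against the other 3, gave 1302 genes, and the strains gave 708. Of the 10 splits, 2 reached 708, which points to a structure of these samples besides the strain. Exchanged labels between the strains are excluded by URA3, whose lowest count in an LP085-Vc library at 6 h was 1178. The differences of that split followed coding length (rho 0.594). LP085-Vc replicate 1 and LP104-17 replicates 1 and 3 each rose with length against the other libraries of their group (rho 0.529, 0.379 and 0.491). LP085-Vc replicates 2 and 3 and LP104-17 replicate 2 each fell with it (-0.55, -0.0964 and -0.582). A smooth trend of single libraries with coding length does not account for the whole split, because 492 genes remained called with it removed. Part of the split may come from that trend. The correction removes only a smooth trend, so other effects tied to length are not excluded. With the trend removed, the real split gave 937.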
